A study of Homo sapiens with 9 samples.

How the data were processed

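Cytoplasmic RNA was sequenced from HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, in 9 libraries. The libraries fell into 3 groups by the treatment named in the labels, with 3 control, 3 emetine and 3 rapamycin libraries. Per the labels' protocols, cells were kept without glutamine for 24 h, incubated with rapamycin or its vehicle for 30 min and then fed with complete medium. Emetine was given at 50 ng/mL for 4 h before harvest, 72 h after feeding. Cytoplasmic extracts were made with a mild detergent, and the libraries were prepared with a stranded kit for polyadenylated RNA. Nothing in the labels said whether the 3 libraries of a group came from separate cultures.

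Both deposited files were tied to all 9 libraries in the labels and named no library inside; which libraries entered each file was not given in the sources used here. The name of the event list holds a code that is also the title of 1 control library but may instead be a confidence level of the event caller. Whether the list rests on all libraries or on fewer is therefore unknown. The first was a merged transcript assembly made by the authors with StringTie 1.2.3 in its merge mode, with GENCODE 19 as the guide annotation, per the file headers. The second was a deposited list of splice events of 6 types, each with 2 isoforms given as chains of exons; the event caller and its settings were not given in the sources used here. Per the submitters' processing notes, Bowtie2, STAR, DESeq2 and StringTie were used and the builds were hg19 and GRCh37, with no role stated for any of them. The measurements in both deposited files were positions of transcripts, exons and isoforms on hg19, counted from 1. The score columns held dots or the constant 1000, so there was no value per library and no read count. The tests planned for rapamycin against control and for emetine against control needed values per library and were not run, and the depth of each library is unknown. The counts below therefore have no replicate error. Shares carry 95% Wilson intervals, which cover counting error over events, exons, introns or genes only. These units are not independent replicates of the experiment.

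Transcript models were sorted into those with a reference transcript ID, those named by a reference gene ID and those without a reference name. Loci were called numbered by the merge where the merge had given them a number of its own, and reference-only where they kept a reference gene ID. A locus number is no measure of expression: 574 reference-only loci had an event. An event was assigned to the reference gene that held the most introns of its isoforms, or, where no intron was annotated, to genes of its locus and strand with a transcript that spanned the event. Of 36748 events, 36169 were assigned to 1 gene, 299 to several genes and 280 to none. Gene names were taken from the files and from a table of gene IDs and symbols, and 443 of the 446 entries of the gene lists were found. PCBP1, SF3B5 and RRAGA were present only as single-exon models named by a gene ID and were left out.

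Skipped exons were compared with the other internal exons of the same genes, and retained introns with the other introns of the same genes. Divisibility of lengths by 3 was tested with Fisher's exact test, two-sided. Median lengths were compared on the log2 scale by a two-sided permutation test with 100000 resamples, whose smallest p is 1e-05. Each of 13 gene lists, fixed before the data were examined, was compared with 100000 random lists of the same size drawn from multi-exon genes and matched on the number of exons in 9 strata (from deciles with ties). The p was two-sided, with 2e-05 the smallest it could be, and was adjusted over the 13 lists by the Benjamini-Hochberg method. The rule for named genes was also fixed beforehand: every member of the lists of nonsense-mediated decay (NMD) factors and of serine and arginine rich splicing factors (SR proteins), the 3 members with the most events of each other list, and the 5 genes with the most events of all. Some results that the rule names are not reported here. Features outside that rule were chosen after their values were seen.

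The planned search for premature stops needed the hg19 sequence, which was not used here. It was replaced by transcript sequences of GENCODE 29, joined by transcript ID for transcripts with the same exon lengths in both annotations and placed on the hg19 exons of the deposited assembly. Where several transcripts covered a position their bases were compared, and 40 of 123911239 such comparisons differed. For each event, 1 isoform was exchanged for the other in the protein-coding transcript with the longest coding part that carried either isoform, out of 41848 such transcripts. The reading frame was followed from the annotated start codon. A stop more than 50 nt before the last exon junction was called premature, which is the usual rule for a stop that triggers NMD. Of 36748 events, 23522 could be read. In the others no coding transcript carried an isoform (10089), part of the sequence was not held by a joined transcript (2119) or the start codon was lost (1018). Shares were compared with Fisher's exact test, two-sided, and for gene lists also with 100000 random draws of whole genes, since events of a gene share their transcripts.

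Alternatives covered the unit of an event, repeated regions, chromosomes, the matching and background of the gene lists, the event type and number, the reference exons and introns, the distance rule for stops, the coding transcript (the shortest coding part, or each direction in its own longest one) and exchanges that change the coding part. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The scripts were tested on simulated data. For the gene lists, 4.0% of 200 unchanged and 100% of 200 enriched lists passed the threshold of 0.05 among 12000 simulated genes. For the medians of 10000 simulated lengths, 5.0% of 100 runs without a shift and 100% of 100 runs with a shift passed. All 400 simulated isoform exchanges with a known stop were read as made.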

Results

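Cytoplasmic RNA of HEK293T cells was sequenced after treatment with vehicle, rapamycin or emetine, in 3 libraries each. Rapamycin inhibits the kinase complex mTORC1, which couples nutrient supply to translation. Emetine blocks translation elongation and thereby NMD, the pathway that degrades mRNAs with a premature stop codon. The study's title asked whether rapamycin modulates NMD. Both files analysed here are tied to all 9 libraries in the labels, hold transcript models and splice events on hg19, and give no read counts. Which libraries entered the event list is unknown, and it may rest on fewer than 9. Depth per library is unknown as well, and rapamycin against control and emetine against control are not analysed here. What follows describes the models of the assembly and the listed splice events without regard to treatment, and none of it can be assigned to a treatment.

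The merged assembly was compared with its reference annotation to see which transcripts it added. All 170728 multi-exon models carried a reference transcript ID, so the merge added no spliced transcript of its own. Of 55945 loci, 25292 (45.2%) were numbered by the merge and the others were reference-only. Reference models were thus kept beyond the loci that the merge numbered. A model alone does not show that its transcript was present in these cells. Of 250326 models, 195685 (78.2%, interval 78.0 to 78.3%) had a reference transcript ID. Another 49949 (20.0%) were single-exon models named by a reference gene ID, and 99.5% of these ran from the first to the last base of the gene. The remaining 4692 models (1.87%) had no reference name, all had 1 exon, and 88.0% of them had no strand. Of 34980 multi-exon reference genes, 19073 (54.5%) were on loci numbered by the merge. By the transcript types of GENCODE 29, 83.0% of the 12989 transcripts annotated as NMD targets were on such loci, against 76.0% of 73926 protein-coding transcripts, and so were 83.8% of 26260 transcripts annotated as retaining an intron. These shares sort annotated transcripts by locus and do not show which of them the cells held.

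Exon skipping was the most frequent kind of listed splice event. Skipping of 1 exon made up 13540 of 36748 listed events (36.8%, interval 36.4 to 37.3%), and skipping of several exons made up 2609 (7.10%). Intron retention followed with 8712 events (23.7%), then alternative 3' splice sites with 5988 (16.3%) and alternative 5' splice sites with 5551 (15.1%). Mutually exclusive exons were rare, with 348 events (0.947%). An event was listed for 10096 of 34980 multi-exon genes (28.9%) and for 9523 of the 19073 on loci numbered by the merge (49.9%). The median was 2 events per gene with an event, 3303 genes had 1 event and 687 had 10 or more. Without the retained introns that lie in no exon of a reference transcript, an alternative chosen after the data were seen, intron retention fell from 23.7% to 11.2% of events.

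**Figure D1:**
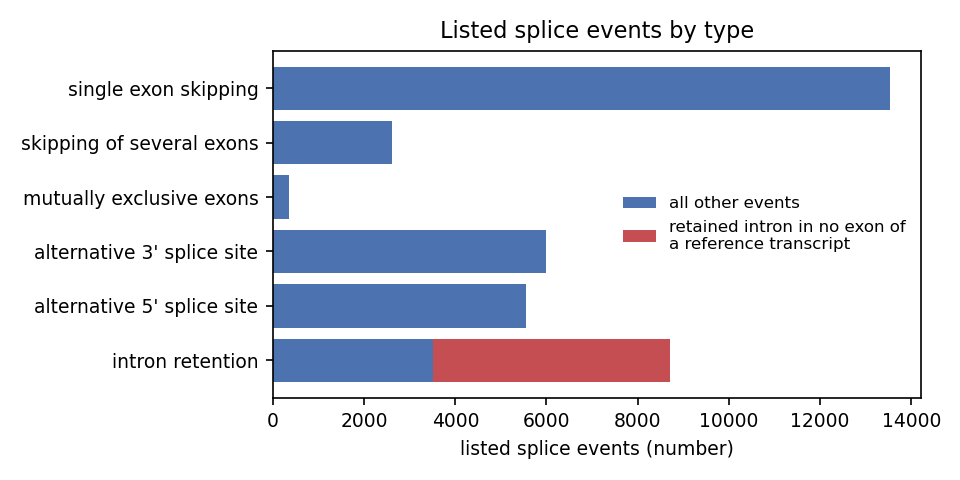
Number of listed splice events (horizontal axis) for each of 6 event types. The part of intron retention whose intron lies in no exon of a reference transcript is drawn apart and holds 5193 of 8712 events.

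The 5 genes with the most events were the antisense gene PCBP1-AS1 with 47, APEX1 with 43, MRPL55 with 42, IRF3 with 40 and MUTYH with 39. PCBP1-AS1 (chromosome 2, 70189395 to 70315978, minus strand) had 22 events of exon skipping and no alternative 3' splice site. In APEX1, the main endonuclease of base excision repair (chromosome 14, 20923350 to 20925927), 24 of 43 events were alternative 5' splice sites and 4 were alternative 3' splice sites. MRPL55, a protein of the mitochondrial ribosome, had 14 events of exon skipping, and IRF3, a transcription factor of the interferon response, had 12 retained introns. MUTYH, a DNA glycosylase, had 12 alternative 3' splice sites and 11 events of exon skipping.

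Genes of RNA decay, splicing and translation had listed events more often than random genes with as many exons. Events were found in 38 of 40 multi-exon genes of the RNA exosome and decay list, against 19.9 expected, and in 40 of 44 described NMD substrates, against 19.8 expected. Among ribosomal proteins it was 61 of 78 against 27.2 expected, among translation factors 36 of 41 against 22, and among core spliceosome genes 31 of 37 against 18.7. The adjusted p of each of these 5 lists was 5.2e-05 in the permutation test, from an unadjusted p of 2e-05, the smallest it can give. Above expectation were also hnRNP proteins with 22 of 24 genes (12.7 expected, adjusted p = 0.000149), exon junction complex genes with 12 of 13 (5.63 expected, adjusted p = 0.000617) and SR proteins with 12 of 13 (5.59 expected, adjusted p = 0.000664). NMD factors had events in 13 of 15 genes against 8.05 expected (adjusted p = 0.0131, permutation test), and mTOR pathway genes in 30 of 44 against 21.8 (adjusted p = 0.0160, permutation test). ATF4 program genes (18 of 29, 13.5 expected, adjusted p = 0.117) and glutamine metabolism genes (15 of 20, 11.7 expected, adjusted p = 0.192) did not differ from random lists. The control list of genes of other tissues lay below expectation, with 5 of 40 genes against 15.9 (adjusted p = 0.000149).

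**Figure D2:**
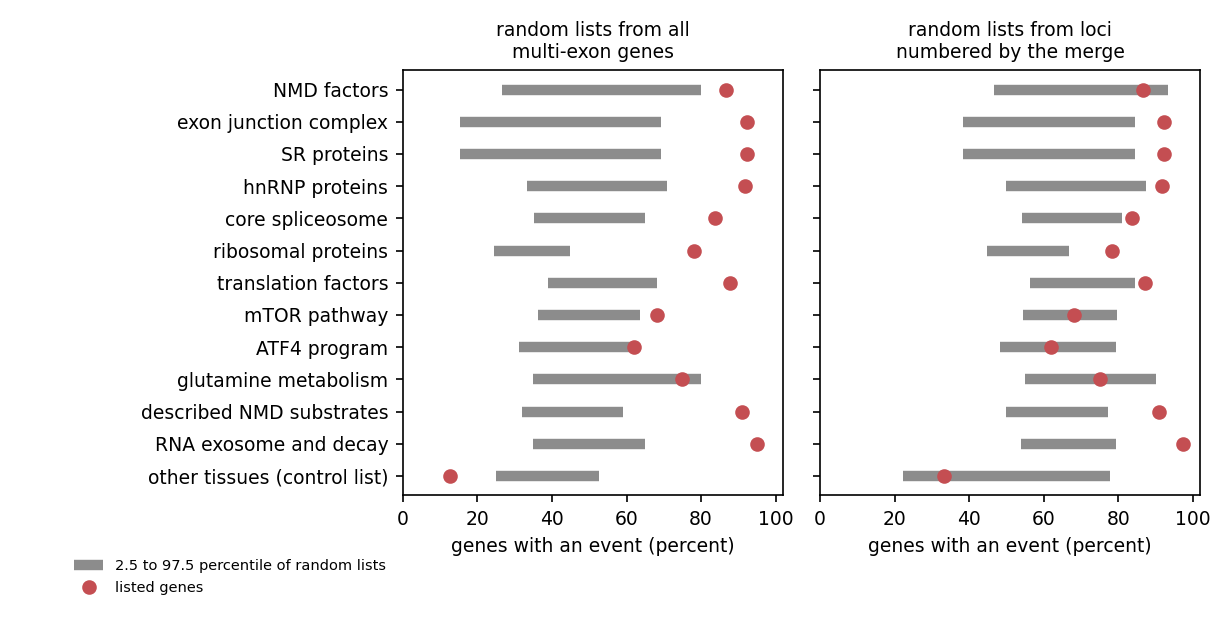
Percent of the multi-exon genes of each list with a listed event (points) beside the middle 95% of random lists matched on exon number (bars), drawn from all multi-exon genes on the left and from loci numbered by the merge on the right. On the left 10 of 13 lists pass the test above expectation and on the right 4 do.

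These lists also differed in the loci they came from. All multi-exon genes of 10 lists were on loci numbered by the merge, as were 39 of 41 translation factors and 39 of 40 genes of the RNA decay list, but 9 of 40 genes (22.5%) of the control list. Random lists were then drawn from such loci alone, an alternative chosen after the data were seen. In this permutation test 4 of the 10 lists passed again: hnRNP proteins (adjusted p = 0.0409), ribosomal proteins (adjusted p = 0.00052), described NMD substrates and the RNA decay list (adjusted p = 0.00026 each). Each of the 10 lists still had more event genes than expected, mTOR pathway genes by little (30 against 29.5). Exon junction complex genes had 1.48 and SR proteins 1.46 times the expected number, in 13 genes each. For hnRNP proteins it was 1.31 times in 24 genes. NMD factors then had an adjusted p of 0.325 and mTOR pathway genes of 1.0, while exon junction complex, SR, core spliceosome and translation factor genes had 0.0719. Matching on the number of transcripts in place of exons left 9 of the 10 lists, without mTOR pathway genes (adjusted p = 0.285), and raised the expectation for ribosomal proteins from 27.2 to 48.9 genes (adjusted p = 0.00639). Without any matching, ATF4 program and glutamine metabolism genes also passed (Fisher's exact test, adjusted p = 0.000275 and 3.04e-05). Counting genes with at least 3 events left 6 of the 10 lists, counting retained introns alone left 5 and counting exon skipping alone left 9, and NMD factors were called in none of these. Of the 44 described NMD substrates, 21 were also in another list. Matched on the number of transcripts, the expectation for these substrates rose from 19.8 to 27.6 genes. Some may have been described as substrates because of an alternative isoform, so part of the excess in this list may follow from its choice. That was not tested.

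Most genes of the NMD machinery had few events. UPF3A had 5 events and the release factor ETF1 had 4. UPF3B, DHX34, NBAS and GSPT1 had 2 each, and UPF1, SMG1, SMG6, SMG8, SMG9 and PNRC2 had 1 each. No event was listed for UPF2, SMG5 or GSPT2, the last of which has 1 exon. The single event of UPF1, the central helicase of NMD, was an alternative 5' splice site that adds or removes 33 nt at 18963881 to 18963913 on chromosome 19.

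SR protein genes had 73 events, 24 of them exon skipping and 20 intron retention, with a median of 5.5 events per gene with an event. SRSF11 had 15, TRA2A 12, SRSF5 8, SRSF10 and TRA2B 7 each, and SRSF7 6. SRSF1 and SRSF4 had 5 each, SRSF2 had 4, SRSF6 had 2, and SRSF3 and SRSF9 had 1 each. SRSF12 and the single-exon gene SRSF8 had none.

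Among the other lists, the genes with the most events were EEF1D (25), EIF4A1 (18) and PABPC1 (17) for translation factors, and RPL17 (18), RPLP0 (16) and RPS2 (15) for ribosomal proteins. EEF1D, a subunit of the elongation factor that recharges eEF1A, had 9 retained introns. In the mTOR pathway list MLST8, a core subunit of the mTOR complexes, had 19 events, 11 of them alternative 3' splice sites, and NPRL2 had 15 and RPS6KB2 14. HNRNPC had 18 events, HNRNPH1 16 and HNRNPUL1 11. WARS1, the tryptophanyl-tRNA synthetase, led the ATF4 program list with 21 events, 9 of them skipping of 1 exon and 8 of several exons, followed by PYCR1 (15) and SHMT2 (8). CNOT2, a subunit of the CCR4-NOT deadenylase, had 19 events, CNOT8 11 and EDC3 8. Among described NMD substrates CIRBP and SNHG1 had 15 each and GAS5 had 13. CIRBP, a cold-inducible RNA-binding protein, had 9 retained introns, and SNHG1 and GAS5, host genes of small nucleolar RNAs, had 4 and 5. The leading genes of the exon junction complex list were ACIN1 (13), MAGOHB (9) and RNPS1 (6), and those of the core spliceosome were SF1 (10), SNRNP70 (8) and EFTUD2 (6). SLC38A9 (7), ASNS (5) and GLUL (4), which makes glutamine, led the glutamine list. In the control list CD8A and COL2A1 had 1 event each.

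Skipped exons were shorter than other internal exons of the same genes, and their length was more often divisible by 3. The length was divisible by 3 in 43.3% of 12721 skipped exons (interval 42.4 to 44.2%) and in 38.4% of 82162 other internal exons (interval 38.0 to 38.7%), an odds ratio of 1.23 (Fisher's exact test, two-sided p = 6.07e-26). Median lengths were 109 nt for skipped and 122 nt for other exons, a log2 difference of -0.16 (permutation test, p = 1e-05, the smallest it can give). The middle of the distribution ran from 76 to 150 nt for skipped exons and from 87 to 167 nt for the others (quartiles). Exons of several transcripts were counted once, and exons of 1 gene are not independent of each other. Coding and non-coding exons were counted alike, so these shares do not measure how often a reading frame was kept.

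Alternative 3' splice sites had a smaller median distance than alternative 5' splice sites, and their spacing was more often a multiple of 3. The distance was divisible by 3 in 46.0% of 5988 alternative 3' events (interval 44.8 to 47.3%) against 37.1% of 5551 alternative 5' events (interval 35.9 to 38.4%), an odds ratio of 1.44 (Fisher's exact test, two-sided p = 3.07e-22). Sites 3 nt apart, the spacing of tandem acceptors, made up 896 of the 5988 alternative 3' events. Without distances of 3 nt the difference was lost, with 36.5% against 36.7% and an odds ratio of 0.995 (Fisher's exact test, two-sided p = 0.920). The most frequent distance between alternative 5' sites was 4 nt, in 190 events (3.42%). Median distances, with those of 3 nt included, were 45 nt for 3' sites and 86 nt for 5' sites, a difference that was not tested. Tandem acceptors 3 nt apart occurred in SRSF10 (24298114 to 24298116 on chromosome 1), in TRA2B (185636224 to 185636226 on chromosome 3) and in GSPT1 (11990640 to 11990642 on chromosome 16), chosen after their values were seen.

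**Figure D3:**
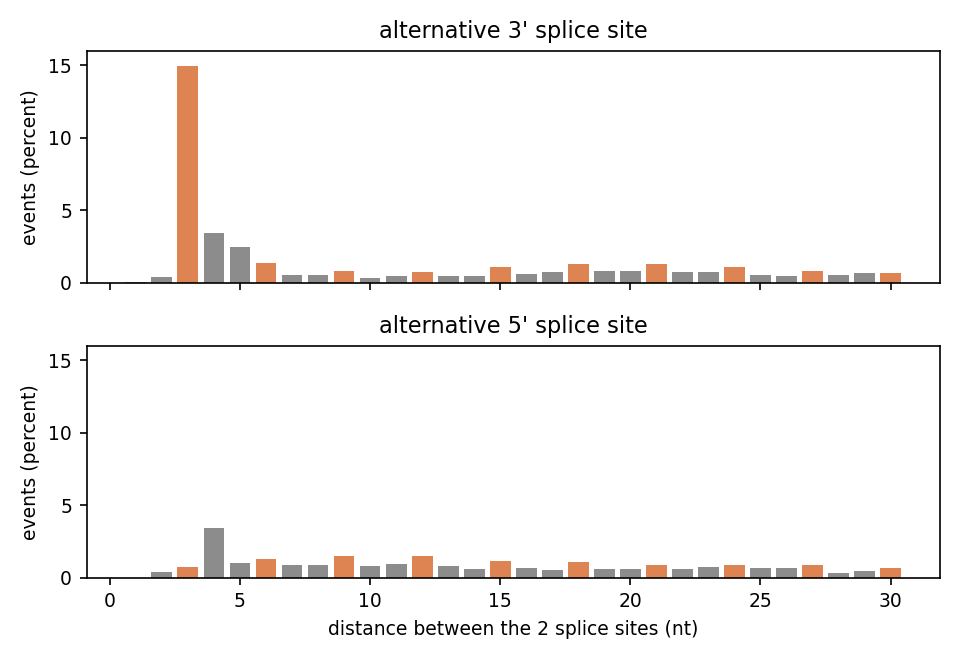
Percent of alternative 3' (top) and alternative 5' (bottom) splice site events at each distance between the alternative sites, up to 30 nt, with multiples of 3 in orange. The bar at 3 nt holds 896 of 5988 alternative 3' events and the tallest bar of alternative 5' events, at 4 nt, holds 3.42%.

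Retained introns were short. Their median length was 549 nt (quartiles 220 and 1352 nt, 8712 introns) against 1261 nt for 63643 other introns of the same genes, a log2 difference of -1.20 (permutation test, p = 1e-05, the smallest it can give). The 8712 introns included 479 absent from the reference, while the other introns compared were all annotated. Of these 479, 401 had the ends of a reference intron on the opposite strand. Of the retained introns, 3519 (40.4%) lay inside an exon of a reference transcript and had a median of 286 nt. The other 5193 (59.6%) lay in no such exon and had a median of 829 nt. Both groups were shorter than other introns of the same genes, by -2.14 and -0.61 on the log2 scale (permutation test, p = 1e-05 each), in a split chosen after the data were seen. In CIRBP all 9 retained introns lay inside an exon of a reference transcript, the shortest of them 45 nt long (1270882 to 1270926 on chromosome 19).

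Exchange of the isoforms created a premature stop in 9776 of the 23522 events that could be read (41.6%, interval 40.9 to 42.2%). Inclusion of an exon did so in 56.9% of 3635 exchanges and skipping in 38.7% of 7032, but this order depended on which coding transcript and which exchanges were read. Among the exchanges that changed the coding part, the gap widened to 71.3% of 2877 for inclusion against 40.3% of 6739 for skipping. With the shortest coding part the order turned, to 35.3% of 5688 for inclusion and 46.7% of 5056 for skipping. With each direction read in its own longest coding transcript, it was 33.0% of 6645 for inclusion and 35.6% of 7676 for skipping. Where the coding part changed, that reading gave 40.3% of 5387 and 38.6% of 7072, without a difference past the threshold (Fisher's exact test, two-sided p = 0.0591). All these alternatives were chosen after the data were seen. Retention of an intron created one in 51.8% of 1237 exchanges and splicing of a retained intron in 33.5% of 1266, and in 39.9% of 1634 and 28.4% of 1567 with each direction read in its own transcript (Fisher's exact test, two-sided p = 6.78e-12). Most premature stops on splicing left the coding part as it was: 80 of the 424 changed it. Among exchanges that changed it, retention created one in 67.0% of 956 and splicing in 15.5% of 517. By event type the share was 44.9% for skipping of 1 exon, against 40.8% for several exons (adjusted p = 0.00267, Fisher's exact test as for the following), 42.5% for intron retention (adjusted p = 0.0422), 37.3% for alternative 5' sites (adjusted p = 4.73e-16) and 37.1% for alternative 3' sites (adjusted p = 1.16e-18). Mutually exclusive exons, at 44.5%, did not pass the test against it (adjusted p = 0.937). Many of these exchanges left the coding part unchanged. Among those that changed it, an alternative chosen after the data were seen, alternative 5' sites turned from below to above skipping of 1 exon (58.0% of 2461 against 49.6% of 9616, adjusted p = 2.91e-13). Intron retention then no longer differed from exon skipping past the threshold (48.9%, adjusted p = 0.654). Removal of a listed skipped coding exon created a premature stop less often than removal of another internal coding exon of the same transcripts. The shares were 40.3% of 6739 and 53.0% of 54073 (Fisher's exact test, two-sided p = 1.91e-85). With the shortest coding part it was 50.7% of 4653. Other exons were not read in those transcripts, so its test against the same 53.0% (Fisher's exact test, two-sided p = 0.00314) compares exons of different transcripts. This is a reading of reference sequences, not a measurement of RNA decay, and which isoform was the more abundant is unknown.

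**Figure D4:**
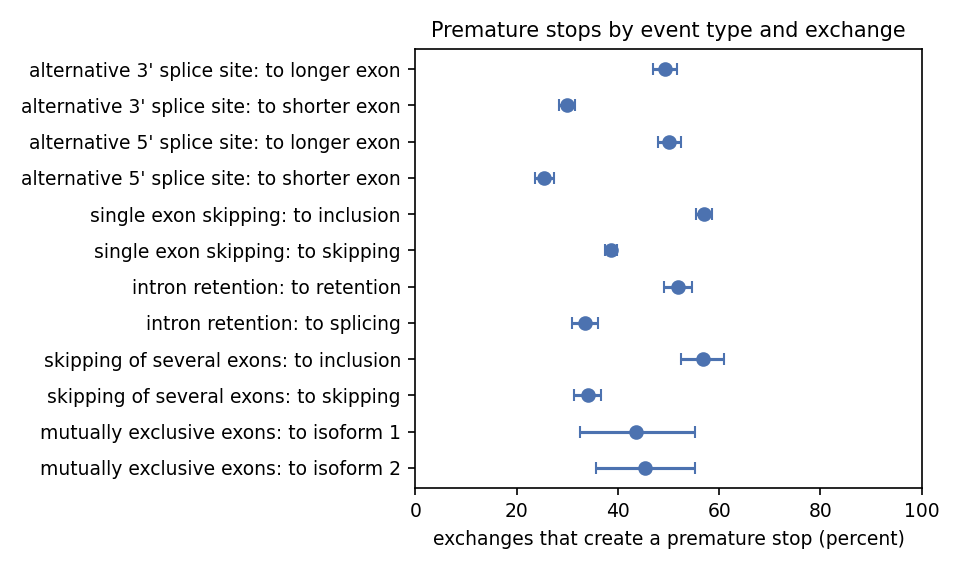
Percent of isoform exchanges that create a premature stop, by event type and by the isoform exchanged to (points), with 95% Wilson intervals (bars). Exchange to inclusion of a single exon stands at 56.9% and exchange to skipping at 38.7%, an order that turned with the shortest coding part (35.3% and 46.7%).

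Exons whose inclusion created a premature stop were listed in 7 SR protein genes: SRSF2, SRSF3, SRSF4, SRSF7, SRSF11, TRA2A and TRA2B. In SRSF3 (ENSG00000112081.12) an exon of 456 nt at 36567598 to 36568053 on chromosome 6, between exons 3 and 4 of the coding transcript, placed a stop 548 nt before the last exon junction. In TRA2B (ENSG00000136527.13) an exon of 276 nt at 185649365 to 185649640 on chromosome 3 placed one 1015 nt before it, and in SRSF7 an exon of 276 nt at 38976040 to 38976315 on chromosome 2 placed one 530 nt before it. The corresponding exons were 104 nt long in SRSF2 (74731854 to 74731957 on chromosome 17, stop 111 nt before the junction) and 195 or 228 nt long in SRSF4 (starting at 29486376 on chromosome 1). All 6 of these exons were carried by transcripts annotated as NMD targets and by no coding transcript. In SRSF5 a retained intron of 1215 nt (70235969 to 70237183 on chromosome 14) created a premature stop. SRSF9 and SRSF10 had none among their 1 and 4 events read, and no event of SRSF6 could be read, including its skipped exon of 268 nt (42087793 to 42088060 on chromosome 20).

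**Figure D5:**
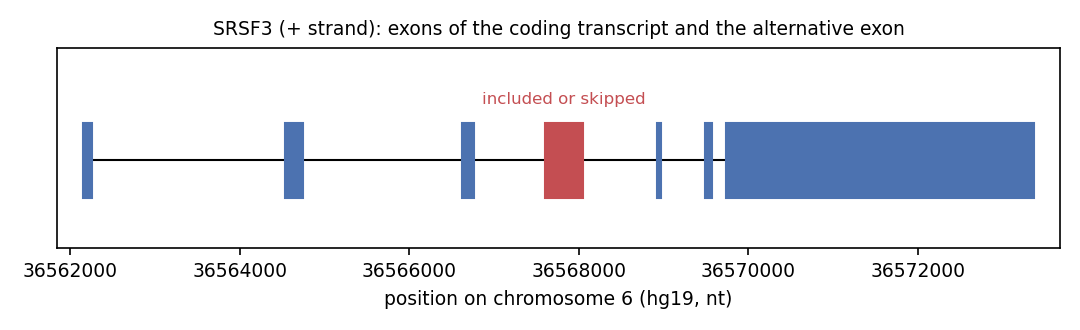
Map of SRSF3 on chromosome 6 (hg19 position on the horizontal axis, plus strand) with the 6 exons of the coding transcript in blue and the exon that is included or skipped, 36567598 to 36568053, in red. The red exon lies between exons 3 and 4.

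NMD factors held premature stops in 7 of the 11 genes with an event that could be read. Inclusion of an exon created one in 5 of them, among them UPF3A, UPF3B, DHX34 and ETF1. The UPF3A exon of 142 nt (115051734 to 115051875 on chromosome 13) did so, while its shorter form of 99 nt did not. In UPF3B an exon of 91 nt (118974557 to 118974647 on chromosome X) placed a stop 475 nt before the last junction. All 4 events of ETF1 and both events of DHX34 created a premature stop. The events of UPF1, SMG1, PNRC2 and GSPT1 that could be read created none.

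The share of events with a premature stop varied between the lists, but no list differed from other genes once whole genes were drawn as units. It was 21.9% of 96 events for hnRNP proteins, 26.8% of 71 for ATF4 program genes and 57.0% of 93 for described NMD substrates, against 41.6%, 41.6% and 41.5% for other genes. Fisher's exact test over events gave adjusted p of 0.000852, 0.0483 and 0.0196, and the permutation over genes gave adjusted p of 0.200, 0.477 and 0.200. HNRNPC had 0 of 17 events with a premature stop in the hnRNP list, and WARS1 had 0 of 18 in the ATF4 program list. For ribosomal proteins it was 35.5% of 172 events, for mTOR pathway genes 33.7% of 92, for translation factors 40.4% of 136, for exon junction complex genes 41.9% of 31, for core spliceosome genes 44.9% of 69, for the RNA decay list 47.1% of 119, for glutamine metabolism 51.9% of 27 and for the control list 20.0% of 5.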

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

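The alternatives for premature stops (the exchanges that change the coding part and the directions read apart included), for retained introns outside transcript exons and for lists drawn from loci numbered by the merge were chosen after the data were seen. No paired analysis was possible because the files give no value per library, although the groups share replicate numbers; for the same reason leaving out each replicate and the other count test and normalization were not run, and the planned search for stops on the genome was replaced. With unknown depth, an event that is not listed may have been too weakly covered. Of the control list, 9 of 40 genes were on loci numbered by the merge. Against lists drawn from such loci, 3 of these 9 had an event and 4.43 were expected (0.677 of the expected number, permutation test, adjusted p = 0.563). With so few genes this test cannot tell whether weak coverage accounts for the shortfall of the whole list.

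Comparisons of exon and intron lengths and of divisibility by 3 in skipped exons kept their direction and their side of the threshold in all alternatives run. The excess of spacings divisible by 3 at alternative 3' sites reversed to an odds ratio of 0.995 without distances of 3 nt, since those distances were removed. Of 10 lists that passed above expectation, 6 passed again with at least 3 events, 5 with retained introns alone and 4 among loci numbered by the merge. The cause was not tested. NMD factors fell below expectation with at least 3 events (0.689 of expected) and core spliceosome genes with retained introns alone (0.964), neither past the threshold.

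Event shares moved with what was counted. With 1 event per gene and type they were 31.9% for skipping of 1 exon, 9.16% for several, 1.36% for mutually exclusive exons, 18.4% for alternative 3' and 17.3% for alternative 5' sites and 21.9% for intron retention. With repeated regions counted once, exon skipping was 35.8% and intron retention 24.5%. Without retained introns outside transcript exons the shares were 42.9%, 8.27%, 1.10%, 19%, 17.6% and 11.2%. Multi-exon models had a reference transcript ID in 100%. Premature stops moved from 41.6% to 46.1% when any stop before the last junction counted, to 37.8% with the shortest coding part, to 39.3% with 1 event per gene and to 48.7% among exchanges that change the coding part, since few of the others create one. Where the coding part changes, the odds ratio of alternative 5' sites against skipping of 1 exon turned from 0.729 to 1.40, and to 1.38 with the shortest coding part. With the longest coding part and the same restriction, the odds ratio of inclusion against skipping rose from 2.10 to 3.67 for 1 exon and from 2.55 to 8.27 for several. The odds ratio of inclusion against skipping (Fisher's exact test) turned from 2.10 to 0.623 for 1 exon and from 2.55 to 0.553 for several with the shortest coding part (0.747 and 0.774 where the coding part changes), and to 0.892 and 0.886 with each direction in its own transcript, where it was 1.07 (p = 0.0591) and 1.25 (p = 0.0220) among exchanges that change the coding part; the cause was not tested. Intron retention against skipping of 1 exon turned from 0.909 to 1.03 with the shortest coding part. Other causes were not tested. Other results outside these comparisons kept their side of the threshold in 131 cases, lost it in 26, gained it in 2 and turned direction from a call in the 11 given here; of the 131, 8 turned direction without passing the threshold in either setting.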

Other observations

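The tests of gene-wide models, of forward splice motifs and of the drawing of whole genes were chosen after the results they bear on had been seen, and the test of opposite-strand introns after the splice motifs had been seen.

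Short exons and transcripts annotated as NMD targets stood out among the events. Exons of 27 nt or less made up 254 of 12721 skipped exons and 1012 of 82162 other internal exons (1.23%), a difference with p = 4.23e-11 in Fisher's exact test, two-sided. Where the exchanged isoform was carried by a reference transcript, 50.4% of 8938 isoforms with a premature stop were carried by transcripts annotated as NMD targets and by no coding transcript, against 3.60% of 12836 isoforms without one. The annotation applies a similar rule to the stop codon, so these shares are not independent of the reading. EIF4A1, the helicase of cap-dependent initiation, had 10 premature stops in 15 events read, and an exon of 125 nt at 7481438 to 7481562 on chromosome 17 placed one 80 nt before the last junction when included.

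Introns absent from the reference were few, and most mirrored an intron of the other strand. They occurred in 1073 of 36748 events (2.92%), as 996 distinct introns, and 69.7% of these (694) had the ends of a reference intron on the opposite strand, against 3 of 58332 annotated introns of the same events. The sequence of 258 such introns from retention events was known, since exons of joined transcripts on either strand held all their bases. Of these 258, 82.6% read CT-AC, the GT-AG motif seen from the other strand, and 4.65% had 8 or more identical bases at their ends. This argues against misalignment at repeats for most of them, but the share was 1.51% among annotated introns, so repeats stay open for a small part. Spliced reads of the opposite strand are therefore a candidate source for most of them, and no biological explanation was tested.

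Of the retained introns, 59.6% lay in no exon of any reference transcript. All of them (100%) lay inside a single-exon model that spans the gene, but so did 99.98% of all 343915 reference introns. This share alone therefore cannot tell whether such models were the source of these events. The highest event number was 343735 for intron retention, against 26336 for skipping of 1 exon. If these numbers count candidates before a filter, nearly every reference intron was a candidate, which such models would give. What the numbers count was not given in the sources used here, so the source was not decided. The median gene with a retained intron in no transcript exon had 13.3% of its introns called retained (quartiles 6.67 and 29.2%), and 463 of 3000 genes had 50% or more. The median met the bound set beforehand against unspliced RNA over whole genes. However, the filter behind the list is unknown and the share counts every annotated intron of a gene. A low share could therefore also arise with such RNA, and this source stays open. Exons of other transcripts covered 50% or more of the intron in 31.5% on the same strand, against 15.3% of a random sample of other introns of the same genes. On the opposite strand they did so in 14.3%, against 1.42%. Either may account for a part. Both shares lay between the bounds set beforehand and smaller overlaps were not counted, so how large a part was not decided. No biological explanation was tested.

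The excess of event genes in lists of RNA decay, splicing and translation may reflect which loci were assembled. Of the 10 lists above expectation, 40% passed the test again when random lists came from loci numbered by the merge, which is consistent with detection of the locus as a part of the excess. These were hnRNP proteins, ribosomal proteins, described NMD substrates and RNA decay genes, with 22 genes against 16.7, 61 against 43.7, 40 against 28.0 and 38 against 26.1. The others of the 10 also had more event genes than expected, without passing. Matched on the number of annotated transcripts instead, the same 4 lists passed as well (adjusted p = 0.00130, 0.00639, 0.000173 and 0.00013), with ribosomal proteins down from 2.24 to 1.25 times the expected number. Expression level was not measured here and stays open.

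A further hypothesis was that introns absent from the reference keep the reading frame. Lengths divisible by 3 made up 39.5% of the 258 from retention events with known sequence, above the share of 1 in 3 (exact binomial test, two-sided p = 0.0404), which met the bound set for it. Most of these introns mirror the other strand, where the frame has no meaning for the gene named, and the 28 with GT-AG or GC-AG ends gave 50% (exact binomial test, two-sided p = 0.0714), so the question stays open.

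Both hypotheses on premature stops were left undecided. Events of SR protein genes created a premature stop in 49.0% of 49 events against 41.5% in other genes (Fisher's exact test, two-sided p = 0.312), and events of NMD factor genes in 53.6% of 28 against 41.5% (p = 0.249). The intervals, 35.6 to 62.5% and 35.8 to 70.5%, include the shares of other genes. An excess could not be shown with so few events.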
